A study of Mus musculus with 21 samples.

How the data were processed

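RNA from mouse hippocampus was sequenced in 21 libraries, all made with the same directional kit per the labels' protocols, so the sequenced strand carries the strand of the transcript. Animals were males of 8 weeks. Groups were taken from the sample titles, which give vector arm (ACSS2 knockdown or control), part of the hippocampus (dorsal, ventral or total), treatment (ethanol or none) and a replicate number. The sample protocol describes an AAV carrying a short hairpin RNA against Acss2 injected into the dorsal hippocampus, whereas the series design text can be read as a systemic route, and the conflict was left open. Neither text describes a vector for the control arm or the time between ethanol and dissection. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these libraries.

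The authors deposited raw counts of reads per gene in 1 table of 24498 genes and 5 summary lines for 21 libraries. Per the submitters' processing notes, STAR 2.5.2a and HTSeq 0.6.1p1 were used with the mm10 genome. The strand setting given to HTSeq is not given in the sources used here. The labels state that the untreated libraries had been published in an earlier series. The summary lines were left out of library sizes and tests and used only for the share of uniquely aligned reads that fell in genes or in no gene. All 21 sample columns were used and 0 were left unused.

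Gene-assigned reads numbered 2819837 to 13240179 in 15 of the ethanol libraries. The other ethanol libraries, dorsal knockdown 5 and ventral knockdown 1, held 5021 and 8744 gene reads. The 4 untreated libraries held 4279 to 221847. Genes took 57.4% to 81% of uniquely aligned reads in the deep ethanol libraries and 0.991% to 1.43% in the untreated ones, with 98.6% to 99% of the latter in no gene. Clopper-Pearson intervals at 95% and floors of 3 counts cover counting error only, because the libraries carry no molecular identifiers.

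Counts were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, after filterByExpr with a minimum count of 10, TMM scaling, estimated dispersions and a robust fit. One model with 6 group means covered 20 libraries, and the single total-hippocampus library entered no test. It gave 15414 tested genes and 9 comparisons. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Levels are TMM-scaled CPM (counts scaled to a library of 1000000), and standard errors were derived from the F statistic.

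Before the data were examined, 32 gene lists were written, of which 30 had at least 2 tested members. The others were a blood list, with 1 tested member, and a list of mitochondrially encoded genes, of which 0 were in the table. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, adjusting over 30 lists within each comparison. List scores were the mean over members of log2 CPM (prior count of 1) minus each gene's mean, over members with a mean of at least 1 CPM. They were computed in the 15 ethanol libraries with over 1000000 gene reads and compared by exact two-sided permutation tests. These score tests, and leaving out single libraries in the list tests, were chosen after seeing the data. A further 3 lists (hypothalamus, lymphocytes and ependymal cells) were added after the data were seen and adjusted among themselves only.

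Named genes were fixed by rule before the data were examined. Acss2 was always named. In the dorsal knockdown comparison after ethanol and in both ethanol comparisons the 8 highest and 8 lowest fold changes were named among called genes with a mean of at least 5 CPM and no overlap between groups, leaving out predicted or clone-named genes, and in other comparisons the 5 highest and 5 lowest. Where nothing passed, the 3 genes with the smallest p were named. From each called list, up to 2 members higher and 2 lower were named among members called over all genes. List members that passed only after adjustment over the list alone were chosen after their values were seen.

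The alternatives tried were RLE scaling, no low-count filter, the replicate number as a block, only the groups compared, DESeq2 1.42.0, leaving out each library in turn, and, chosen after seeing the data, leaving out the shallow or the untreated libraries. Other splits of the same libraries were drawn up to 100 times per comparison. The fits were tested on simulated counts with 200 changed genes. A 4-fold change was called in 85% of genes (14485 tested) in the simulated dorsal knockdown comparison and 81% (14520 tested) in the ventral one, and a 2-fold change in 17% and 12%. In the simulated ethanol comparisons a 4-fold change was called in 13% (control, 14493 tested) and 4% (knockdown, 14485 tested). The simulated genes varied independently of each other, unlike real genes.

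Strand was examined with the GENCODE M21 annotation of the same build in Python 3.11.15. Of the symbols in the table, 23607 (96.4%) matched it, and 5700 genes had an exon overlapped by an exon on the opposite strand.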

Results

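The data measured messenger RNA in the hippocampus of mice given ethanol by intraperitoneal injection at 2 g per kg, as a 20% solution, or left untreated. One arm carried a short hairpin RNA against Acss2, the nuclear and cytosolic enzyme that makes acetyl-CoA from acetate, the product of ethanol breakdown. After ethanol there were 5 dorsal and 4 ventral knockdown libraries, 3 dorsal and 4 ventral control libraries and 1 knockdown library of total hippocampus. Without ethanol there were 2 dorsal libraries in each arm. Gene reads per library ranged from 2819837 to 13240179 in 15 ethanol libraries. Dorsal knockdown 5 and ventral knockdown 1 held 5021 and 8744 gene reads. The untreated libraries held 4279 to 221847.

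Acss2 (ENSMUSG00000027605.18, protein coding, chromosome 2, 155517948 to 155585724, plus strand, mm10) was lower in the dorsal knockdown libraries than in dorsal controls after ethanol by less than the test required. In libraries with over 1000000 gene reads it stood at 34.9 ± 16.0 CPM (SD, n = 4) in dorsal knockdown and 63.0 ± 3.41 CPM (SD, n = 3) in dorsal control, 55.3% of the control mean, and each of these knockdown libraries lay below each control (exact permutation p = 0.0857, two-sided, smallest possible 0.0286). The 4 knockdown values were 51.0, 46.2, 20.5 and 21.9 CPM. In ventral hippocampus Acss2 was 49.2 ± 20.7 CPM (SD, n = 3) in knockdown and 57.3 ± 3.27 CPM (SD, n = 4) in control (exact permutation p = 0.343), with single knockdown values of 33.1, 72.5 and 42.0 CPM. The total-hippocampus knockdown library held 66.0 CPM. Dorsal knockdown 5 had 2 Acss2 reads and ventral knockdown 1 had 0, which allows up to 179.5 CPM there. All 4 untreated libraries had 0 Acss2 reads. Few of their reads fell in genes, and those followed the opposite-strand gene more than exon length, as given below. In untreated control 2 they followed the gene's own level about as closely (Spearman rho 0.398 against 0.403). These zeros therefore set no upper limit on Acss2, and the knockdown could not be checked in them. Over all 5 dorsal knockdown libraries the mean was 62.1 ± 62.4 CPM (SD, n = 5), because the 2 reads of dorsal knockdown 5 gave 171 CPM (exact permutation p = 0.536, n = 5 and 3). The edgeR log2 fold change of Acss2 over all libraries was -0.80 (SE 0.35, adjusted p = 0.912) in dorsal and -0.25 (SE 0.34, adjusted p = 1) in ventral hippocampus. Before adjustment over all genes, the edgeR p of this gene, named beforehand, was 0.0306 in dorsal and 0.474 in ventral.

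**Figure D1:**
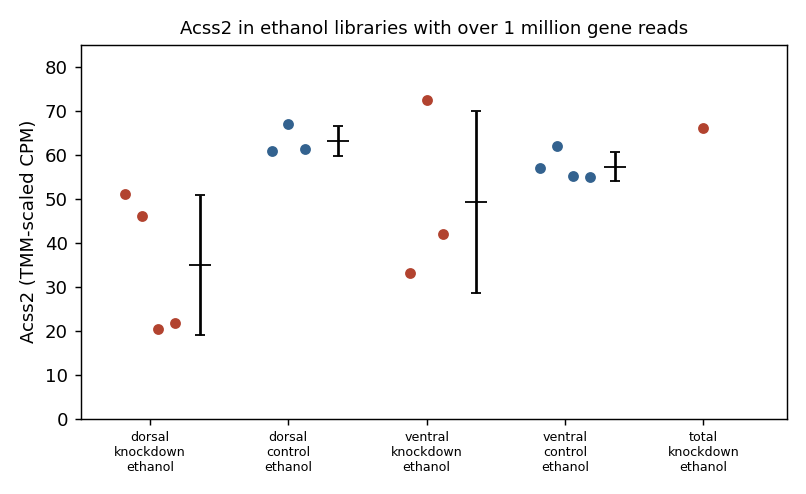
Acss2 in TMM-scaled CPM (vertical axis) for each ethanol library with over 1000000 gene reads (points), by group, with the mean and SD beside groups of more than 1 library. Dorsal knockdown libraries lay between 20.5 and 51.0 CPM and dorsal controls between 60.9 and 67.0 CPM.

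In dorsal hippocampus after ethanol, interferon, microglia and reactive astrocyte genes were higher in the knockdown libraries, with wide spread between them. All 24 measured members of the interferon-stimulated and antigen presentation list were higher (median log2 fold change 2.63), and 20 of them passed when adjusted over the list alone, 0 over all genes. Among them the class I molecule H2-D1 stood at 63.2 ± 44.5 against 12.9 ± 4.18 CPM and the peptide transporter Tap1 at 18.5 ± 19.5 against 3.81 ± 0.744 CPM (SD, n = 4 and 3). All 19 microglia genes were higher (median 0.79), 9 of them past adjustment over the list alone, including the complement genes C1qb (129 ± 68.4 against 43.1 ± 8.45 CPM) and C1qa (126 ± 79.8 against 41.1 ± 9.13 CPM). All 11 reactive astrocyte genes were higher (median 2.34), 8 past adjustment over the list alone, among them the intermediate filament genes Gfap (1878 ± 1536 against 470 ± 117 CPM) and Vim (271 ± 279 against 51.7 ± 5.73 CPM). The interferon score was -0.95, 0.63, 3.08 and 1.68 in dorsal knockdown 1 to 4, against -1.21 to -0.58 in the dorsal controls. Without dorsal knockdown 3 the interferon median was 1.78 and the reactive astrocyte median 1.21, and that library's reactive astrocyte score was 3.20 against -0.28 to 0.90 in dorsal knockdown 1, 2 and 4. Dorsal knockdown 3 also had the highest hypothalamus score, 2.90. Of the cholesterol synthesis and SREBP target genes, 26 of 27 were lower (median -0.30, and -0.13 with DESeq2), and 0 passed alone. Relative to the median of all tested genes this was -0.30 with edgeR and -0.36 with DESeq2. Astrocyte genes (12 of 16 lower, median -0.18) and oligodendrocyte precursor genes (8 of 10 lower, median -0.10) were not called (adjusted p = 0.161 and 0.207 by camera of limma).

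With camera at the preset correlation, adjusted p was 2.92e-24 for the interferon list, 4.31e-18 for microglia, 3.09e-10 for reactive astrocytes and 5.47e-07 for cholesterol genes. With an estimated correlation the adjusted p was 0.209 for each of these 4 lists. Exact permutation p of the list scores was 0.0857 for the interferon list, 0.0571 for microglia, 0.0857 for reactive astrocytes and 0.0571 for cholesterol genes (n = 4 and 3, adjusted 0.514, smallest possible 0.0286). Immediate early genes, which neuronal activity induces, had a median of 0.89 with 28 of 33 higher (adjusted p = 0.564 with an estimated correlation), and of 0.47 without dorsal knockdown 4. Their scores ran from -1.17 to 1.98 in dorsal knockdown and from -0.24 to 0.25 in dorsal control (exact permutation p = 0.514). Of these, Ptgs2 (113 ± 80.5 against 15.6 ± 9.19 CPM) and Nptx2 (183 ± 137 against 35.9 ± 11.5 CPM) passed adjustment over the list alone. Genes of glutamatergic synapses (26 of 34 lower, median -0.26), presynaptic release (17 of 20 lower, median -0.26) and inhibitory synapses (13 of 19 lower, median -0.18) were called with the preset correlation and not with an estimated one (adjusted p = 0.564 for each). Without single libraries these medians ran from -0.45 to -0.06, from -0.40 to -0.17 and from -0.31 to -0.09. With DESeq2 the 3 medians over all libraries were -0.12, -0.11 and -0.03. Relative to the median of all tested genes they were -0.36, -0.34 and -0.26 with DESeq2, against -0.26, -0.26 and -0.18 with edgeR. Dorsal knockdown 2, ventral knockdown 3 and ventral control 1, the 3 ethanol libraries with the smallest share of Rn45s reads, had the 3 lowest scores both for glutamatergic synapses (-0.72, -0.57 and -0.72) and for immediate early genes (-1.17, -0.68 and -1.17). The markers of neighbouring tissue moved with these groups. Neocortex genes had a median of -0.52 (7 of 8 lower) and thalamus genes of -0.33 (8 of 10 lower). Adjusted p was 0.216 and 0.564 by camera with an estimated correlation. With DESeq2 the medians were -0.42 and -0.06. Relative to all tested genes they were -0.65 and -0.30 with DESeq2, against -0.53 and -0.33 with edgeR. Without dorsal knockdown 4 the neocortex median was -0.975. That library had a neocortex score of 0.50, against -0.66 to -0.44 in dorsal knockdown 1 to 3. Ribosomal protein genes had a median of 0.22, with 70 of 78 higher (adjusted p = 0.852 with an estimated correlation), which turned to -0.04 without dorsal knockdown 2 and was 0.46 with DESeq2. Relative to the median of all tested genes it was 0.22 with edgeR and 0.23 with DESeq2.

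No single gene was called in this comparison: edgeR gave 0 of 15414 genes, with 756 at an unadjusted p under 0.05, and DESeq2 gave 3. The genes with the smallest p were Jchain, the joining chain of antibodies (log2 fold change 3.97, SE 0.71, adjusted p = 0.19 by edgeR), the lymphocyte receptor Ly9 (5.39, SE 1.13, adjusted p = 0.487) and the complement component C4b (2.69, SE 0.58, adjusted p = 0.487). The number of lists called at the preset correlation was not specific to the knockdown. Of the 56 splits of these 8 libraries, 41 called at least as many as the 11 lists of the real split. Which lists they called was not examined, so this count does not bear on any single list. Without a single library Jchain was called (adjusted p = 0.0341 by edgeR without dorsal knockdown 1), and the calls of thalamus, ribosomal protein and inhibitory synapse genes ended (highest adjusted p = 0.233, 0.243 and 0.0857 by camera of limma).

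**Figure D2:**
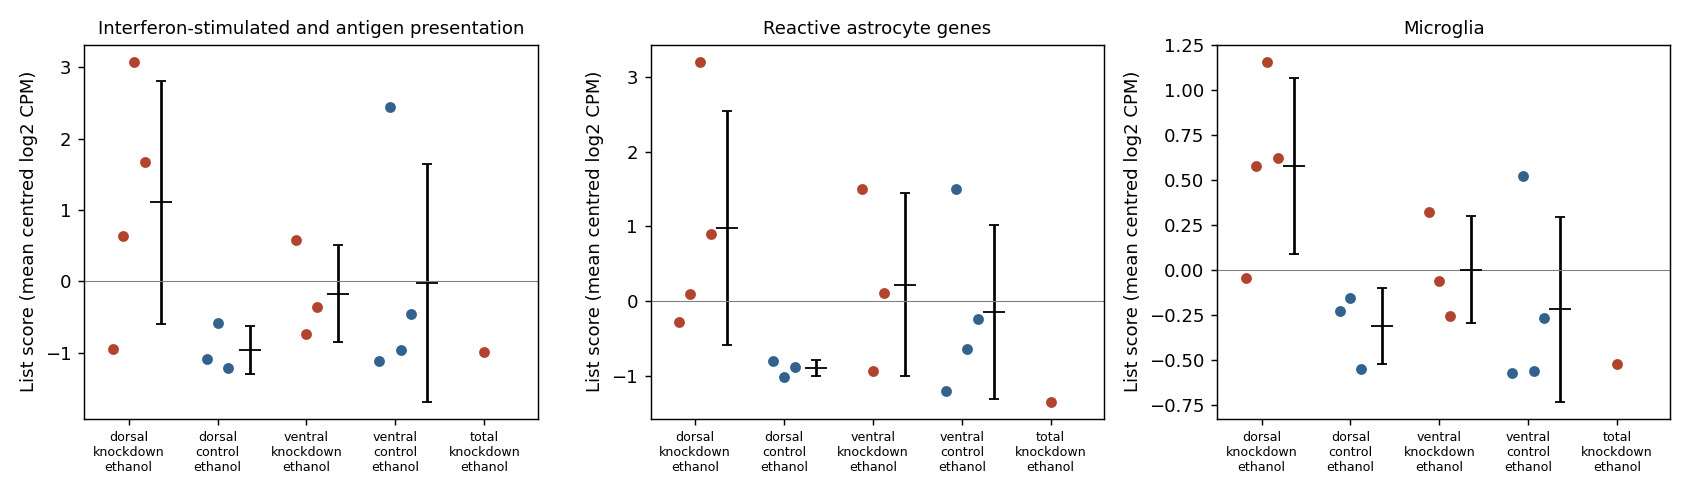
List scores (mean centred log2 CPM, vertical axes) of the interferon, reactive astrocyte and microglia lists for each ethanol library with over 1000000 gene reads (points), with mean and SD. Dorsal knockdown 3 had the highest interferon score, 3.08, and ventral control 2, at 2.45, lay above the other dorsal knockdown libraries.

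In ventral hippocampus after ethanol, 1 gene differed between the arms. Pld5, a member of the phospholipase D family (chromosome 1, 175962306 to 176275312, minus strand, mm10), stood at 1.96 ± 0.878 CPM in the 3 knockdown libraries with over 1000000 gene reads and at 20.7 ± 9.94 CPM in 4 control libraries (SD; 0 reads in ventral knockdown 1, which allows up to 179.5 CPM; log2 fold change -3.40, SE 0.46, adjusted p = 0.0022 by edgeR). Genes of the choroid plexus, the tissue that secretes cerebrospinal fluid, were lower in knockdown in 12 of 12 cases (median -4.61), and 11 passed adjustment over the list alone. Their control mean rested on ventral control 4, with a list score of 5.32 against -1.08 to 1.16 in the other ventral controls, and without it the median was -1.28. The thyroid hormone carrier Ttr stood at 4319 ± 8161 CPM in control. Markers of ventral hippocampus were lower in 8 of 8 cases (median -1.47, and -0.38 without ventral control 1), with Coch at 3.73 ± 1.92 against 13.5 ± 4.42 CPM and the serotonin receptor Htr2c at 26.1 ± 8.74 against 91.1 ± 60.7 CPM. Markers of CA1 pyramidal neurons were higher in 7 of 8 cases (median 0.67, and 0.32 without ventral knockdown 3), with Wfs1 at 405 ± 273 against 75.6 ± 32.1 CPM (SD, n = 3 and 4). Wfs1 was also in the list of dorsal hippocampus markers, and Coch in that of CA3 and mossy neurons. Calls of these lists were therefore not independent.

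Dentate granule (10 of 10 lower, median -0.92, and -0.09 without ventral control 3), CA3 and mossy (8 of 9 lower, median -0.51, range -1.60 to -0.19 without single libraries) and mature oligodendrocyte markers (13 of 14 lower, median -0.47, and 0.13 without ventral control 4) were also called by camera at the preset correlation, as were microglia (14 of 19 higher, median 0.13), dorsal hippocampus markers (median 0.18), neocortex (median 0.45) and chaperone genes (16 of 18 lower, median -0.22). Without single libraries these 4 medians ran from 0.05 to 0.50, from -1.12 (without ventral knockdown 3) to 0.68, from 0.17 to 0.76 and from -0.45 to -0.08. With an estimated correlation no list was called, and adjusted p was 0.0625 for CA1, 0.302 for choroid plexus, 0.266 for ventral markers and 0.266 to 0.985 for the others. Of 35 splits of these libraries, 24 called at least the 10 lists of the real split. The Pld5 call ended with only the ventral groups in the fit (adjusted p = 0.227 by edgeR) and without the untreated and shallow libraries (0.0971), and DESeq2 called 2 other genes. Without ventral control 1, where Pld5 stood at 5.95 CPM, edgeR called 64 genes, and the list calls other than choroid plexus, ventral markers and CA1 each ended without some single library.

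Dorsal and ventral hippocampus were compared within each arm after ethanol. In controls, CA1 markers were higher in dorsal tissue (median 1.27, 6 of 8 higher), with Wfs1 at 265 ± 92.8 against 75.6 ± 32.1 CPM and Mpped1 at 327 ± 20.0 against 112 ± 78.5 CPM (SD, n = 3 and 4). Ventral markers (7 of 8 lower, median -0.93) and dentate markers (10 of 10 lower, median -1.04) were lower there. The activity-induced transcription factor Nr4a2 was higher in dorsal controls (112 ± 23.3 against 31.5 ± 12.2 CPM). Of 30 lists, 12 were called by camera at the preset correlation, and with an estimated correlation adjusted p was 0.0878 for CA1 and 0.603 to 0.604 for the others. Choroid plexus (median -3.21) and interferon genes (median -1.80) were lower in dorsal controls, and these differences ended without ventral control 4 (median -0.10, adjusted p = 0.965 by camera of limma) and ventral control 2 (median -0.12, adjusted p = 0.75 by camera of limma). The call of ventral markers ended without each of 4 of the 7 libraries (highest adjusted p = 0.54 by camera of limma, median up to 0.11), and that of dentate markers without dorsal control 2 or ventral control 3 (highest 0.273, median -0.25 without the latter). edgeR called 0 genes, with 840 at an unadjusted p under 0.05, and DESeq2 called 4. Pld5 (log2 fold change -2.67, SE 0.45, adjusted p = 0.0654 by edgeR) and Prph (3.91, SE 0.73, adjusted p = 0.209 by edgeR) had the smallest p.

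In the knockdown arm, immediate early genes were higher in dorsal than in ventral hippocampus (31 of 33 higher, median 1.44), and 21 passed adjustment over the list alone. Their scores were 1.60, -1.17, 0.16 and 1.98 in dorsal knockdown 1 to 4, against -0.68 to -0.17 in ventral knockdown (exact permutation p = 0.314), so dorsal knockdown 2 lay below all 3 ventral libraries. Fosb stood at 128 ± 136 against 11.4 ± 4.16 CPM and Nptx2 at 183 ± 137 against 34.0 ± 13.2 CPM (SD, n = 4 and 3). Interferon (median 1.75, and 0.73 without dorsal knockdown 3) and microglia genes (median 0.57) were higher in all members, and fibroblast and meningeal genes (median -1.36) were lower in all 12. The meningeal median turned to 0.11 without ventral knockdown 4, where its call ended, and whose score was 2.33 against -0.22 and -1.01 in ventral knockdown 2 and 3. At the preset correlation 14 lists were called. With an estimated correlation adjusted p was 0.199 for immediate early genes and 0.216 to 0.527 for the others. Ventral hippocampus markers were among the lists called higher in dorsal tissue (median 0.69), against the region labels. That call ended without dorsal knockdown 2 or ventral knockdown 3. Dentate markers were lower in dorsal tissue (median -0.665), as in controls. Markers of CA1 and of dorsal hippocampus were not called, so these markers did not bear out the region labels in the knockdown arm. edgeR called 0 genes, with 430 at an unadjusted p under 0.05, and DESeq2 called 0. The genes with the smallest p were Zfp36, Apol9a and Igf2os (adjusted p = 1 by edgeR for each).

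The difference between the knockdown effects of the 2 regions was tested as an interaction. Prph, a neuronal intermediate filament gene (chromosome 15, 99055174 to 99058978, plus strand, mm10), was the only gene called (log2 difference -6.26, SE 0.97, adjusted p = 0.0339 by edgeR). In libraries with over 1000000 gene reads it stood at 1.67 ± 1.32 CPM in dorsal knockdown and 9.77 ± 3.37 in dorsal control, and at 8.94 ± 7.07 in ventral knockdown and 0.610 ± 0.309 in ventral control (SD, n = 4, 3, 3 and 4). The higher means thus lay in dorsal control and ventral knockdown. A different dissection was not tested and cannot be told apart from a knockdown effect here. Interferon genes had a higher dorsal than ventral knockdown effect in all 24 cases (median difference 3.38, adjusted p = 0.306 with an estimated correlation). It was 1.98 without ventral control 2, whose interferon score was 2.45 against -1.11 to -0.45 in the other ventral controls. CA1 markers had a median difference of -0.83 (adjusted p = 0.101 with an estimated correlation), and of -0.35 without ventral knockdown 3, with Wfs1 at -3.22 (SE 0.63). The Prph call ended with RLE scaling, with only the ethanol groups, without the shallow libraries (adjusted p = 0.202 by edgeR), and without each of 12 of the 16 libraries compared. It also ended with the replicate number as a block within the vector arm.

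The untreated libraries differed from the ethanol ones in where their reads fell. Genes took 0.991% to 1.43% of their uniquely aligned reads, and 54.5% to 68.7% of these gene reads lay in the 5700 genes with an opposite-strand exon, against 24% to 29.7% in ethanol libraries. Grin1os, an antisense gene overlapping the glutamate receptor gene Grin1 (chromosome 2, 25291220 to 25298925, plus strand, mm10), had 79 to 3084 reads in untreated libraries, where Grin1 had 2 to 54. In the deep ethanol libraries Grin1os had 0 to 12 reads and Grin1 1519 to 8443. The same held for Chn1os3 against Chn1 and Peg3os against Peg3.

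**Figure D3:**
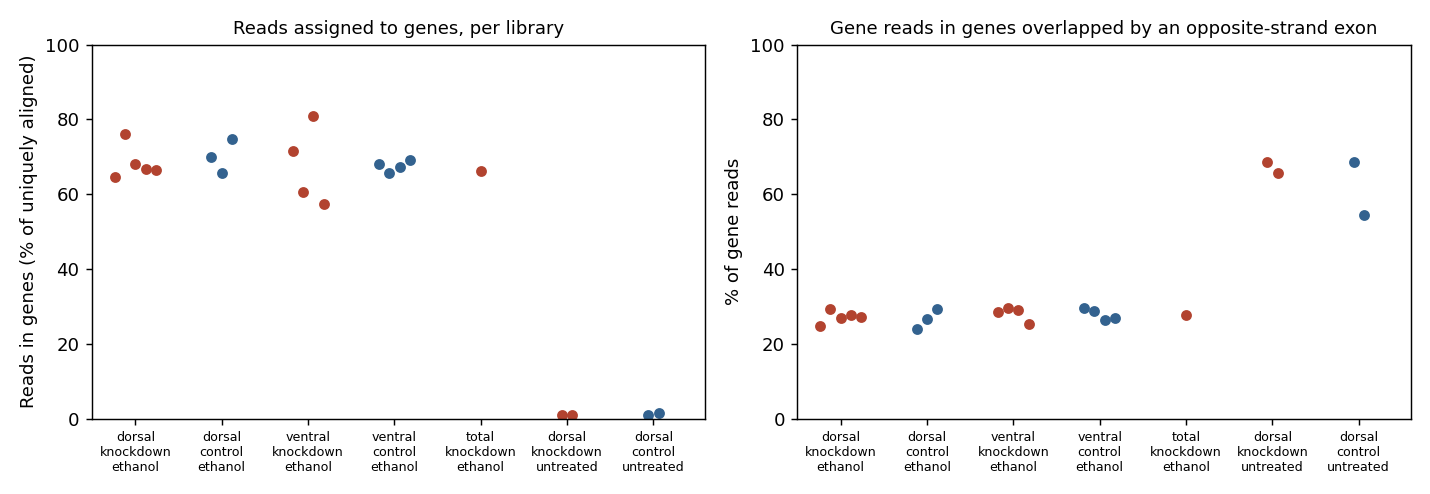
Left, reads in genes as a percent of uniquely aligned reads. Right, the percent of gene reads in genes overlapped by an opposite-strand exon. Points are single libraries by group, and the untreated libraries lie at 0.991% to 1.43% and at 54.5% to 68.7%.

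The comparisons of ethanol with untreated libraries therefore set 2 series and 2 patterns of strand against each other as well as ethanol against none, and none of the genes they call can be assigned to ethanol. In the control arm edgeR called 1732 genes higher and 2076 lower after ethanol. Of those lower, 63.1% had an opposite-strand exon, against 23.3% of those higher and 26.8% of those not called. The lowest included Gpr39, Peg3os, Zim3, Mir1900, Cdr1, Ccdc73, Grin1os and Chn1os3. Grin1os stood at 0.560 ± 0.154 CPM with ethanol and 30451 ± 13595 CPM without (SD, n = 3 and 2). Among the highest were C1qtnf4 (166 ± 24.5 CPM), Abhd17a (148 ± 17.5 CPM), Atp5j2, Cox7a2, Map1s, Ttc9b, Fosl2 and Pcyt2, all with 0 reads in the untreated libraries. Nuclear-encoded genes of oxidative phosphorylation were higher in 30 of 32 cases (median 2.25), as were ribosomal protein genes (69 of 78, median 1.99) and astrocyte genes (13 of 16, median 1.24). Camera called these 3 lists at the preset correlation and none with an estimated one (adjusted p = 0.929 for each). With DESeq2 the calls were 455 higher and 1990 lower, and with RLE scaling 1110 and 2359.

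In the knockdown arm 2264 genes were called higher and 1522 lower by edgeR, and 68.3% of those lower had an opposite-strand exon against 24.4% of those higher. The lowest were Dear1, Eps8l3, Peg3os, Mir1900, Cdr1, Ccdc38, Chn1os3 and Arhgap20os. The highest were Lars2, Slc25a3, Adam11, Dennd5a, Slc25a22, Rpl8, Wsb2 and Rap1gds1, all with 0 untreated reads. Presynaptic release genes were higher in 20 of 20 cases (median 2.21), with Syn2 at 832 ± 359 against 59.1 ± 29.1 CPM (SD, n = 5 and 2), and inhibitory synapse genes in 19 of 19 (median 2.83). Relative to the median of all genes these were -0.39 for presynaptic genes and 0.23 for inhibitory synapse genes with edgeR, and 1.45 and 1.81 with DESeq2. Camera called 7 lists at the preset correlation and 0 with an estimated one (adjusted p = 0.837 to 0.94). RLE scaling gave 281 higher and 1931 lower, DESeq2 102 and 1859, the dorsal knockdown groups alone 326 and 1253, and leaving out untreated knockdown 1 gave 423 calls. Both arms shared 982 of the genes called higher and 1424 of those called lower, against 254 and 205 for independent lists, and the earlier series is common to both arms.

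Reversal of the ethanol response could not be read from calls, since the dorsal knockdown called 0 genes. The covariance of the ethanol and knockdown fold changes over all genes was -0.224, against -0.134 (range -0.155 to -0.110) in 20 simulations of unchanged groups with the same shared control. Their correlation was -0.0868, against -0.104 (range -0.118 to -0.0875) in the simulations. The covariance lay beyond its range and the correlation just beyond its range the other way. The simulated groups all shared the same mean levels, without the strand difference of the untreated libraries that shaped the real ethanol fold changes. Neither value can therefore decide on reversal, which stays open. The knockdown effect in untreated dorsal hippocampus gave 0 calls by edgeR, with 1355 genes at an unadjusted p under 0.05, and 1 by DESeq2. Ptdss1, Sept3 and Thy1 had the smallest p (adjusted p = 0.461 by edgeR for each). Camera called 8 lists there at the preset correlation, among them presynaptic release (20 of 20 lower, median -1.70, against -0.81 over all genes, and -0.70 with DESeq2), and none with an estimated one (adjusted p = 0.251 to 0.976). Relative to the median of all tested genes the presynaptic median was -0.89 with edgeR and -0.90 with DESeq2. The knockdown-by-ethanol interaction gave 0 calls by edgeR, with 1121 genes unadjusted, and 2 by DESeq2. Ptdss1, Rpe and Alas1 had the smallest p there (adjusted p = 0.674 by edgeR for each). Excitatory, presynaptic and inhibitory synapse genes were called by camera at the preset correlation (medians 1.38, 1.36 and 2.04) and not with an estimated one (adjusted p = 0.948 to 0.991). The median of all genes there was 0.96 with edgeR, and with DESeq2 the 3 medians were 0.13, 0.56 and 0.76. Relative to the median of all tested genes they were 0.415, 0.395 and 1.08 with edgeR and 0.544, 0.972 and 1.18 with DESeq2. Leaving out untreated knockdown 1, so that 1 library of 4279 reads stood for its group, gave 288 and 80 calls.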

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

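The tests of opposite-strand counting, of sequencing depth and of a single library behind the ventral markers were chosen only after the results were seen. So was the rule that a single library is set aside only where the list scores of the 2 groups lie apart. The other tests in this part were written before. In 90 sets of values from single groups 8 values stood far from the rest of their group, where chance picks out about 1 in 20, or 4.5.

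The untreated libraries carried reads outside genes at 99%, 99%, 99% and 98.6% of uniquely aligned reads, above 42.3%, the highest ethanol library. Low depth is argued against, since 1 untreated library had 15557875 uniquely aligned reads, above the ethanol median of 13118756. Genomic DNA is argued against as well: untreated counts followed the level of the opposite-strand gene more than exon length, with rho larger by at least 0.169 across genes in the 3 untreated libraries with the most gene reads. The lowest share of gene reads in genes with an opposite-strand exon was 54.5%, which is consistent with counting on the strand opposite to the kit's. In untreated control 2, which had the most gene reads of these, rho was 0.403 with the opposite-strand gene and 0.398 with the gene's own level. Reads of that library were therefore not tied to the opposite strand alone. No biological explanation was tested, because treatment, series and counting are confounded here.

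Immune genes were higher in the dorsal knockdown, and for microglia genes a single library is argued against as the whole source: each of the 4 knockdown scores (-0.04 to 1.16) lay above each control (-0.55 to -0.15), and without each library in turn the highest adjusted camera p was 1.26e-10 at the preset correlation (0.209 for the full list with an estimated one). Interferon genes fall outside the rule, as dorsal knockdown 1 (-0.95) lay among the controls, but the other 3 (0.63 to 3.08) lay above each control, so more than 1 library raised them. Blood cannot be told apart, since 1 blood gene was tested, at a log2 fold change of 0.0108. Injection and vector cannot be told apart from loss of Acss2: the labels describe no vector in the control arm, and within the 4 dorsal knockdown libraries the microglia score had a rho of -1 with Acss2 (exact permutation p = 0.0833, the smallest possible). This met the bound written against vector, but that bound was wrong, because a larger dose of vector could lower Acss2 and raise microglia genes as well.

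Region markers differed between ventral knockdown and control. A single library stays open for the ventral markers: their highest adjusted camera p was 0.031 without each ventral library in turn, but the median shrank from -1.47 to -0.38 without ventral control 1. The call needs the preset correlation (adjusted p = 0.266 with an estimated one), and the scores of the 2 groups overlapped. Hypothalamic tissue cannot be told apart: the hypothalamus list had a median of -0.19, which met the bound written against it, but 4 members were higher and 4 lower, from -2.83 to 1.26, so the median decides nothing. A different dissection between animals stays open and was not tested. In the knockdown arm the ventral markers were higher in dorsal than in ventral tissue (median 0.69, called at the preset correlation only).

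Other splits of the same libraries did not exclude chance for the 2 genes called or for any number of lists. Where 0 genes were called, every split reaches that number, so the count of splits says nothing. In the dorsal knockdown comparison that was 56 of 56 splits, with 33 genes in the highest other, and 41 of 56 gave at least its 11 lists, with 20 in the highest other. In the ventral knockdown comparison 8 of 35 splits gave at least the 1 gene (highest other 103) and 24 gave at least the 10 lists (highest other 21). In the region interaction 16 of 100 splits gave at least the 1 gene (highest other 432) and 21 gave at least the 15 lists (highest other 21). For dorsal against ventral in controls 17 of 35 splits gave at least the 12 lists (highest other 19), and 35 of 35 reached 0 genes (highest other 26). In the knockdown arm 22 of 100 gave at least the 14 lists (highest other 18), and 100 of 100 reached 0 genes (highest other 40).

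Single libraries stood apart from their group. Dorsal knockdown 5 had 5021 gene reads against 7416053 to 9029427. Dorsal knockdown 4 had a CA1 score of -0.44 against 0.33 to 0.48 and a dorsal marker score of -1.14 against 0.15 to 0.37. Ventral control 2 had Ly9 at 3.801 CPM against 0.372 to 0.503, Apol9a at 1.46 CPM against 0 to 0.126, and a neocortex score of 0.42 against -0.73 to -0.54. Ventral control 1 had Pld5 at 5.95 CPM against 23.7 to 27.0. Ventral control 4 had a score of 0.31 for genes of ethanol, acetate and acetyl-CoA metabolism, against -0.06 to -0.003.

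The arms differed unequally between regions for Prph (-6.26) and, by camera at the preset correlation only, for 15 lists. Region markers did not bear out the region labels in the knockdown arm. A different dissection therefore cannot be told apart from a knockdown effect in these differences. The median differences were 0.84 for immediate early genes, -0.21 for excitatory synapses (-0.08 without ventral knockdown 4), -0.42 for presynaptic release (-0.18 without ventral knockdown 2), -0.35 for cholesterol genes, 3.38 for interferon genes (1.98 without ventral control 2), 2.24 for reactive astrocytes (0.92 without dorsal knockdown 3), 0.78 for microglia (0.44 without ventral control 2), -0.35 for astrocytes (-0.06 without ventral knockdown 2), 0.58 for mature oligodendrocytes (0.03 without ventral control 4), 4.18 for choroid plexus (1.19 without ventral control 4), -0.83 for CA1, 0.52 for CA3 and mossy neurons and -0.40 for dorsal markers (-0.35, 1.85 and 0.49 without ventral knockdown 3), 1.39 for ventral markers (0.41 without dorsal knockdown 2) and -1.18 for neocortex. The call ended without each of 10 of the 16 libraries for astrocytes (highest adjusted p = 0.354 by camera of limma), and of 4 for mature oligodendrocytes (0.81), dorsal markers (0.382) and excitatory synapses (0.061). It also ended without dorsal knockdown 4 for immediate early genes (0.131) and without ventral knockdown 3 for reactive astrocytes (0.0665).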

How the results depend on the processing

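Leaving out shallow or untreated libraries and the permutation of list scores were chosen after seeing the data; the cause was not tested for any change given here. Calls in the dorsal knockdown comparison (0) became 1 without the filter, 3 with DESeq2 and 0 to 1 without single libraries. In the ventral one (1) they became 2 with RLE, 4 without the filter, 0 with only the groups compared, 0 without the 4 untreated and 2 shallow libraries, 2 with DESeq2, and 1 to 64 without single libraries (7 without ventral knockdown 3, 64 without ventral control 1). The untreated knockdown comparison gave 1 with DESeq2 and 0 to 288 without single libraries. Ethanol in controls (3808) gave 2445 with DESeq2 and 2156 to 3430 without single libraries. Ethanol in knockdown (3786) gave 2212 with RLE, 1579 with only the groups compared, 1961 with DESeq2 and 423 to 3677 without single libraries. The ethanol interaction gave 2 with DESeq2 and 0 to 80 without single libraries. The region interaction (1) gave 0 with RLE, 2 without the filter, 0 with only the groups compared, 0 without the shallow libraries, 0 without the untreated and shallow libraries, 4 with DESeq2 and 0 to 27 without single libraries (27 without ventral knockdown 3). Dorsal against ventral gave 1 without the filter, 4 with DESeq2 and 0 to 16 without single libraries in controls (16 without ventral control 1), and 0 to 3 in knockdown (3 without dorsal knockdown 2, 1 without ventral knockdown 3).

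Same-numbered dorsal and ventral libraries correlated at -0.157 to 0.341, within the range of differently numbered pairs. With so few libraries, these correlations cannot tell whether same-numbered libraries came from the same animal, so pairing stays open. With the number as a replicate block the calls became 2 in the dorsal knockdown comparison, 8 in the ventral one and 10 in the region interaction, or 0 there with the block within the vector arm.

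List calls over all comparisons (83) became 0 with an estimated correlation and 15 with fry, and those of the 4 two-group ethanol comparisons (47) became 0 by exact permutation of list scores, where a smallest p of 0.0286 leaves little room for a call over 30 lists. Shared genes of the ethanol response with and without knockdown (2406) ranged from 334 without untreated knockdown 1 to 2379 without dorsal knockdown 2, with 1582 without untreated control 1. Acss2 in dorsal against ventral in control after ethanol turned from 0.14 to -0.0263 with RLE and -0.0292 with DESeq2, and Enpp2 in dorsal against ventral in control after ethanol turned from -2.59 to 0.226 with the block within the vector arm and, over single libraries left out, ranged from -3.11 to 0.355, the latter without ventral control 4. Of the other values for named genes, 62 lost and 25 gained a call. Scaling with RLE moved the median of all genes to 0.16 in the dorsal knockdown comparison and to 0.29 in the region interaction. With DESeq2 the median in the dorsal knockdown comparison was 0.33. That value covered genes without the low-count filter, so the set of genes changed as well as the scaling. DESeq2 medians given relative to all tested genes used the filtered genes only. Called lists kept the sign of their median with both scalings in both ethanol knockdown comparisons. The medians of astrocyte genes in dorsal against ventral controls (0.14, then -0.02 with RLE) and of CA3 genes in the knockdown arm (0.21, then -0.005 with DESeq2) turned. In the untreated knockdown comparison astrocytes turned from -1.45 to 0.125 and microglia moved from 0 to 0.69 with DESeq2. Relative to the median of all genes, 4 of 7 called lists turned for ethanol in the knockdown arm. So did 1 of 8 in the untreated knockdown comparison and 1 of 14 in dorsal against ventral knockdown. Few gene reads limit the 2 shallow libraries through depth, and the untreated libraries through the small share of reads in genes. Untreated knockdown 2 was also shallow, with 422290 uniquely aligned reads.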

Other observations

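The relation of list scores to Acss2 across the knockdown arm was not among the tests fixed before the data were examined. The test of vector delivery in this part was chosen only after that relation was seen. Of the relations within a region, only that of microglia genes in dorsal knockdown, given above, had a bound written before. The 3 added lists were written after the data were seen.

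Marker genes of other tissue varied between libraries of a group. Hypothalamus genes were higher in the dorsal knockdown in 8 of 8 cases (median 1.24, adjusted camera p = 0.0176 with an estimated correlation), and dorsal knockdown 3 held a score of 2.90 against -0.45 to 0.48 in the other dorsal knockdown libraries. The hypothalamus score rested on 5 genes, and its exact permutation p was 0.114 (n = 4 and 3, adjusted 0.228). Cxcr6 and Ptprc, the 2 measured members of the lymphocyte list, were both higher there (adjusted camera p = 0.0176 with an estimated correlation). So small a list cannot tell lymphocytes from microglia, whose genes were higher as well. Ependymal genes, which mark the lining of the ventricles, were lower in the ventral knockdown in 7 of 7 cases (median -2.03, adjusted camera p = 0.0616 with an estimated correlation), and ventral control 4 had a score of 2.64.

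Ribosomal RNA precursor reads of Rn45s took 0.6254% to 20.7% of gene reads in the deep ethanol libraries. Dorsal knockdown 2, ventral knockdown 3 and ventral control 1, with 1.17%, 1.08% and 0.6254%, had ribosomal protein scores of 0.76, 0.79 and 0.44.

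Across the 8 knockdown-arm libraries with over 1000000 gene reads, the interferon score fell as Acss2 rose (Pearson r = -0.911, exact permutation p = 0.00139, adjusted 0.00278; Spearman rho = -0.857, exact permutation p = 0.0107, adjusted 0.0214). Without dorsal knockdown 3 and 4, the libraries farthest from the median Acss2 on the log2 scale used for r, it was -0.738. Reactive astrocyte genes gave r = -0.898 (exact permutation p = 0.00139, adjusted 0.00278), rho = -0.952 (exact permutation p = 0.00114, adjusted 0.00456) and r = -0.952 without those libraries. Microglia genes gave r = -0.815 (exact permutation p = 0.0149, adjusted 0.0199), rho = -0.762 (exact permutation p = 0.0368, adjusted 0.0491) and r = -0.528 without them. Without the total-hippocampus library the microglia relation was no longer called (r = -0.768, exact permutation p = 0.0466, adjusted 0.0621; rho = -0.714, exact permutation p = 0.0881, adjusted 0.117). Immediate early genes gave r = -0.353 (exact permutation p = 0.389), among 4 lists in each of 3 sets of libraries. Over 15 ethanol libraries the interferon r was -0.701, and -0.273 without the same libraries. The permutations across the knockdown arm mixed dorsal, ventral and total libraries. Their Acss2 differed, with means of 34.9 CPM in dorsal and 49.2 CPM in ventral knockdown and 66.0 CPM in the total-hippocampus library. A hypothesis is that vector delivery may have varied between animals, lowering Acss2 and raising immune genes together, but loss of Acss2 itself would also give the r of -0.738, so the 2 cannot be told apart. Within the 4 dorsal and within the 3 ventral libraries the interferon score ranked exactly opposite to Acss2 (exact permutation p = 0.0833 and 0.333, the smallest possible). Ventral control 2 had an interferon score of 2.45 at 62.0 CPM of Acss2, so immune genes also varied without any loss of Acss2.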
